A study of Macaca mulatta and Macaca fascicularis with 6 samples.

How the data were processed

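Droplet 3' single-cell RNA sequencing was analysed for 6 libraries, which the labels place in 2 lines (rhesus macaque, labelled male, and cynomolgus macaque, labelled female) and 3 stages (naive ESCs, day 2 EBs, day 4 EBs). Per the submitters' processing notes, Cell Ranger, STAR and Seurat were used with the rhesus genome build rheMac8; their versions and the role of each tool are not given in the sources used here. The authors deposited filtered matrices of raw UMI counts per gene and barcode for each library, and no step after counting is recorded for these values. Reads of both species were counted against the rhesus build, so a cynomolgus gene that differs in sequence can be undercounted. Per the labels' protocols RNA was made into libraries with a Chromium 3' kit, which counts molecules near the 3' end of a transcript. The growth text of the labels pairs male with XX and female with XY, which contradicts the usual meaning of both.

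The feature tables hold 24037 gene IDs, of which 15436 have a symbol and 8601 do not. A table of IDs gave names to 1128 more. No coordinates are given here, since the chromosome table used here is of another assembly. SOX17, XIST, KIT and some other fixed genes had no matched ID and were left out, and the X-inactivation list had 0 matched members, so 28 lists were tested. Genes with near-identical copies, such as RPS4Y1 and RPS4X, can share reads, and their values are uncertain to that extent.

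Cells were kept with at least 500 genes, at most 20% mitochondrial UMIs and no doublet call. Scrublet (in scanpy 1.11.5) was run per library with an expected rate of 0.8% per 1000 barcodes. It called 0.0198% and 0.0134% of barcodes in the naive and day 2 libraries of the rhesus line and 0.0952% in the naive library of the cynomolgus line, far under the expected rate, so doublets remain in these libraries. In the other 3 it called 2.22% to 3.21%, also under the expected rate, so doublets may remain there too. Raw counts were summed over the kept cells of each library (at least 72838476 UMIs). Cells were not used as replicates. TMM factors ran from 0.959 to 1.08.

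Stages were compared with edgeR 4.0.16 (R 4.3.3): quasi-likelihood test on the sums of all 6 libraries, line as covariate, filterByExpr by stage, Benjamini-Hochberg adjusted p under 0.05, with 2 residual degrees of freedom and a prior of 3.11. Lines were compared the same way with stage as covariate. Fold changes are log2 and their error is the SE implied by the F statistic; levels of named genes are TMM-scaled CPM, as mean ± SD of the 2 lines. Ratios of Y-linked genes, the check for free RNA and the checks between libraries use CPM without TMM scaling. The pairing rests on the labels, as libraries of the same line share a replicate number: deviations of same-line libraries from the stage means correlated by 0.101 (naive and day 2), 0.229 (naive and day 4) and 0.473 (day 2 and day 4) over 5966 genes. Gene lists were tested with limma 3.58.1 camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, whose test of whether a list moves 1 way called 0 of 28 lists in each comparison; p-values were adjusted over 84 tests. Comparisons of day 2 and of day 4 with naive share the naive libraries, and their calls are not compared with each other.

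The germ cell gate required at least 1 UMI of at least 2 of TFAP2C, PRDM1 and NANOS3; SOX17 was part of the planned gate and was dropped for want of a matched ID, which made a looser planned gate, any 2 of the genes, identical to the main gate. Counts were summed per library over gated and other cells and tested with the library as covariate, without the gate genes. Shares were also computed with each cell thinned to 4000 UMIs, leaving out shallower cells (all naive cells stayed, with 6811 and 8091 cells at day 2 and 6896 and 5628 at day 4). Cells of each line were clustered in scanpy (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, leidenalg 0.10.2) without integration of the lines. A cluster was named where at least 3 fixed markers of a type were enriched and no other type had more markers among its 10 leading genes. As a check for free RNA, TTR was at 123 to 281 CPM in EB cells outside the endoderm-like clusters and at 0.160 and 0.267 CPM in naive libraries. Free RNA, remaining doublets or low expression in these cells can each give such levels, and they were not told apart.

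Genes were named by a rule fixed, like the groups, tests, lists and most alternatives, before the data were examined: per comparison the 10 called genes with a symbol and the largest fold in each direction, the same direction in each line and an average log2 CPM of at least 4; up to 4 measured members of each list with the largest fold, called or not; and the gate, core pluripotency and Y-linked genes. From that pool a subset is given, and 2 of its genes are not reported here. The alternatives were RLE size factors, no low-count filter, DESeq2 1.42.0, all deposited barcodes, sums thinned to the smallest total, each library left out, the replicate block left out, only the libraries compared, a minimum fold of 2, other gates, depth-matched cells and other cluster settings. Each test was run on simulated counts with 200 genes changed 2, 4 or 8-fold: edgeR recovered 25.9% and 65.0% of genes changed 4 and 8-fold for day 2 against naive, 53.9% and 89.3% for day 4 against naive and 71.9% and 91.5% between lines. Beside these edgeR called 3, 19 and 4 unchanged genes. The 200 changed genes are far fewer than the 3302 and 2469 called in the data for day 2 and day 4 against naive. The adjustment is stricter when fewer genes change, so these rates need not hold for the data. Intervals cover counting error only.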

Results

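Single cells were sequenced from 6 libraries of macaque embryonic stem cells (ESCs) and of embryoid bodies (EBs), the free-floating aggregates in which stem cells differentiate, grown toward primordial germ cell-like cells. For each of 2 lines, labelled as rhesus macaque and cynomolgus macaque, there was 1 library of naive ESCs, 1 of day 2 EBs and 1 of day 4 EBs. Naive ESCs were held on mouse feeder cells in LIF with inhibitors of the kinases GSK3, MEK, JNK and p38. The libraries held between 4200 and 9005 barcodes and between 74084854 and 100289794 UMIs. The median barcode held 17976.5 and 22345 UMIs in the naive libraries of the rhesus and cynomolgus lines, and between 9460 and 11981.5 in the 4 EB libraries. Cell filters kept 38257 of 38870 barcodes. With 1 library per line and stage, a p-value between stages is set against how far the changes over all stages disagree between 2 lines. Constant differences between the lines are removed by the covariate. In these lines species, labelled sex and handling go together. A p-value between lines rests on the same kind of disagreement, and a p-value for gated cells on how far the gated difference varies over 4 EB libraries. None measures the spread between cultures of a single line.

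The sex labels were checked first. The rhesus line is labelled male and the cynomolgus line female, while the growth text of the labels pairs male with XX and female with XY. RPS4Y1, a Y-linked ribosomal protein gene, was at 1990.2 CPM in naive cells of the rhesus line and 2014 CPM in those of the cynomolgus line, and it had a UMI in at least 99.4% of cells in every library. Over the 9 Y-linked genes with at least 20 UMIs in each library, the median log2 ratio of the cynomolgus to the rhesus line, from CPM without TMM scaling, was -0.22 in naive cells, -0.41 at day 2 and -0.07 at day 4. RPS4Y1 differed between the lines by 0.09 ± 0.11 (log2 ± SE, edgeR adjusted p = 0.789). The libraries are therefore called by their labelled species, and no comparison here is read as male against female.

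Day 2 EBs were compared with naive cells to find the genes that change at the start of differentiation. Most of the mesoderm and amnion or trophoblast genes measured rose, HAND1 and the endoderm gene TTR rose from near 0, and SOX2, a core pluripotency factor, fell to under 1% of its level in naive cells. HAND1, a transcription factor of extraembryonic and cardiac mesoderm, rose from 0.0829 ± 0.0264 CPM to 2162 ± 684 CPM (SD, n = 2 lines). TTR, which encodes the transport protein transthyretin of visceral endoderm and liver, rose from 0.22 ± 0.0818 to 2082 ± 83.9 CPM. SOX2 fell from 428 ± 77.9 to 3.17 ± 0.0799 CPM. USP44, a deubiquitinase of the primed pluripotency list, fell by 6.11 ± 0.23 on the log2 scale.

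Of the 12 measured mesoderm genes, 9 rose and 0 fell, with HAND1 up by 14.59 ± 0.53 and HAND2, its close relative, up by 11.61 ± 0.68 (log2 ± SE; edgeR adjusted p = 0.00264 and 0.0057). SNAI2, a repressor active in migrating mesenchyme, rose by 5.12 ± 0.42. Of 14 amnion and trophoblast genes 10 rose and 0 fell, among them the transcription factors GATA3 (5.67 ± 0.61) and MSX2 (4.70 ± 0.38) and the keratin gene KRT18 (3.48 ± 0.49). Of 14 endoderm genes 7 rose and 2 fell; TTR rose by 13.26 ± 0.44 and APOB, the apolipoprotein of liver and yolk sac, by 8.06 ± 0.75. Of 14 fibroblast genes 9 rose and 0 fell, with POSTN, a secreted matrix protein, up by 9.22 ± 1.09, and of 14 mesenchymal genes 10 rose and 0 fell, with CDH11, a mesenchymal cadherin, up by 5.23 ± 0.34, FN1 by 3.72 ± 0.27 and COL4A1 by 3.41 ± 0.28. Of 12 epithelial genes 6 rose and 0 fell, including KRT19 (3.77 ± 0.43). Of 9 endothelial and blood genes 3 rose and 0 fell, with FLI1 up by 6.53 ± 0.70 and RUNX1 by 3.00 ± 0.36. Among genes of large change outside these lists were HAPLN1, a hyaluronan link protein (13.26 ± 0.80), NTS, the neurotensin precursor (11.21 ± 1.27), and SPINK1, a protease inhibitor (11.18 ± 0.54). INSL4, a placental relaxin-family gene, had 0 UMIs in both naive libraries and stood at 3.52 CPM in the rhesus line and 668.9 CPM in the cynomolgus line at day 2. Adjusted over the list alone, the numbers that rose were 10 for mesoderm, 12 for amnion and trophoblast, 8 for endoderm, 12 for fibroblast, 11 for mesenchymal, 6 for epithelial and 4 for endothelial and blood genes. On the same basis 1 amnion and trophoblast gene and 3 endoderm genes fell. VTCN1, of the amnion list, went from 51.1 ± 5.59 to 3.21 ± 4.37 CPM (SD, n = 2 lines). Of the endoderm list FOXA2 went from 19.4 ± 20.3 to 3.87 ± 1.4 CPM and HHEX from 18.7 ± 16 to 0.437 ± 0.451 CPM.

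Of 11 core pluripotency genes 0 rose and 6 fell, with SOX2 down by -7.04 ± 0.49 and L1TD1, an RNA-binding protein of ESCs, by -2.90 ± 0.66 (log2 ± SE; edgeR adjusted p = 0.00702 and 0.0373). POU5F1, which encodes OCT4, went from 219 ± 34.4 to 27.2 ± 32.4 CPM (SD, n = 2 lines). Its change of -3.45 ± 1.03 missed the threshold in edgeR (adjusted p = 0.0676), as the lines differed in size (-5.51 in the rhesus and -2.28 in the cynomolgus line), and it passed in DESeq2 and when either day 2 library was left out. Of 16 primed pluripotency genes 0 rose and 10 fell, including DNMT3B, a de novo DNA methyltransferase (-3.33 ± 0.28), and the transcription factors ZIC2 (-5.94 ± 0.78) and OTX2 (-5.83 ± 1.37). Of 12 neural ectoderm genes 0 rose and 6 fell, with LHX2 at -4.84 ± 0.46. Of 20 S phase genes 0 rose and 13 fell, by smaller amounts: PCNA, the replication clamp, by -1.35 ± 0.17 and TYMS, thymidylate synthase, by -1.78 ± 0.22. Of 11 immediate-early genes 0 rose and 4 fell, with FOSB at -4.77 ± 0.76. Of 19 glycolysis and hypoxia genes 0 rose and 8 fell (BNIP3, a mitophagy receptor, -3.17 ± 0.56), and of 17 cholesterol synthesis genes 0 rose and 3 fell (DHCR7, the last reductase of the pathway, -1.77 ± 0.26). CAV1, the main protein of caveolae, and ACTG2, a smooth muscle actin, fell by 7.75 ± 0.36 and 5.91 ± 0.68. Adjusted over the list alone, 8 core, 10 primed, 8 neural, 15 S phase, 6 immediate-early, 10 glycolysis and 1 cholesterol genes fell.

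Of 9 early germ cell genes 3 rose and 0 fell: PRDM1, the repressor BLIMP1 (1.90 ± 0.46), NANOS3, an RNA-binding protein of germ cells (4.64 ± 0.98, with only 4 UMIs in naive cells), and ARID5B (4.55 ± 0.35). PRDM1 and OTX2 missed the threshold when any of the 4 libraries of naive cells and day 2 EBs was left out, and TET2 without either naive library or the day 2 library of the rhesus line. Without either naive library NANOS3, L1TD1, FOSB and ZIC2 missed it. Without the naive library of the rhesus line BNIP3, DHCR7, FLI1, LEF1, LHX2, PCNA, POSTN, RUNX1 and TYMS missed it too. TFAP2C, a transcription factor of germ cells and trophoblast, did not pass (1.78 ± 1.45, edgeR adjusted p = 0.397). Of 14 naive pluripotency genes in the annotation 6 had enough counts to be measured. Of these 3 rose and 1 fell, and the 3 included TBX3 (6.02 ± 0.88) and IL6ST, the signalling receptor of LIF (4.23 ± 0.47). In the naive libraries KLF4 was at 30.8 CPM, and IL6ST, TBX3, NLRP7, DNMT3L and TFCP2L1 were at 1.04 CPM or less. Of the primed list DNMT3B and USP44 were at 333 and 116 CPM there, and ZIC2 and FGF5 at 1.24 and 0.0468 CPM. The name naive is that of the labels, and most naive genes measured had counts near 0 in these cells and little room to fall. Low counts here cannot show that a gene was off: NANOG, of the core list, was at 0.254 CPM in naive cells and the G2M gene BIRC5 at 0.206 CPM. Of 19 fixed naive genes 5 had no matched ID. Of 10 BMP target genes 4 rose and 1 fell, with BAMBI, a decoy receptor, up by 4.36 ± 0.17, and of 9 WNT target genes 1 rose and 1 fell, with LEF1 up by 4.63 ± 0.53. Of 10 DNA methylation genes 1 rose and 1 fell, the first being TET2, a methylcytosine dioxygenase (2.44 ± 0.39). In the other fixed lists, 0 rose and 1 fell of 6 late germ cell genes, 0 and 2 of 7 primitive streak genes, 1 and 1 of 4 neural crest genes, 1 and 1 of 12 FGF and ERK targets, 1 and 1 of 8 STAT3 targets, 3 and 1 of 12 unfolded protein response genes, 0 and 3 of 13 p53 targets, 1 and 3 of 20 G2M genes, and 0 and 2 of 10 Y-linked genes.

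edgeR's quasi-likelihood test called 3302 of 14663 genes between day 2 and naive, 1883 higher and 1419 lower at day 2. With camera's preset correlation 15 of 28 lists passed, 7 up (mesoderm, endoderm, amnion and trophoblast, fibroblast, endothelial and blood, epithelial, mesenchymal) and 8 down (core and primed pluripotency, neural ectoderm, immediate-early, S phase, G2M, glycolysis, cholesterol). The preset-correlation adjusted p ran from 5.48e-06 for S phase to 0.0459 for G2M genes, and 0 lists passed with an estimated correlation, where the adjusted p of these lists ran from 0.547 to 0.617. Single omissions ended the call for G2M (any library), cholesterol (day 2 or naive, rhesus line), endothelial and blood (naive of the rhesus or day 2 of the cynomolgus line) and epithelial genes (day 2 or naive, cynomolgus line). The count of called genes fell with any single library left out. Each such fit leaves 1 library in a stage and fewer residual degrees of freedom, so the fall cannot show that the calls rest on that library.

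**Figure D1:**
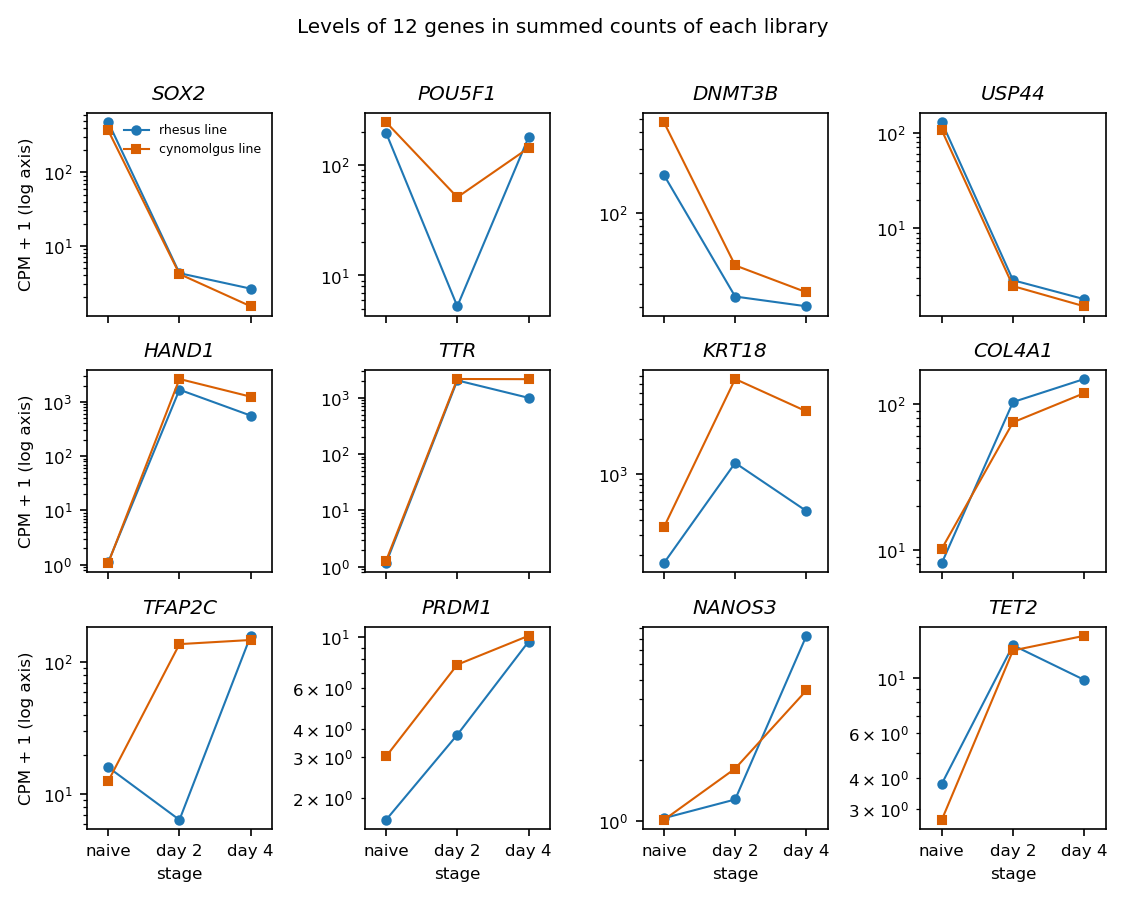
Level of 12 genes (CPM + 1, log axis) in summed counts of each library against stage, with circles for the rhesus line and squares for the cynomolgus line, 1 library per point. HAND1 and TTR rise from near 0 to over 1000 CPM in both lines by day 2, SOX2 and USP44 fall, and TFAP2C at day 2 is at 5.41 CPM in the rhesus and 137 CPM in the cynomolgus line.

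Day 4 EBs were compared with day 2 EBs to follow later steps. No gene passed the test, so the values that follow are differences without a call, with an adjusted p of 0.751 for each named gene. NANOS3 stood at 0.546 ± 0.382 CPM at day 2 and 5.35 ± 2.71 CPM at day 4 (SD, n = 2 lines), a log2 difference of 3.27 ± 0.75 (SE). DND1, an RNA-binding protein of germ cells, differed by 1.72 ± 0.38, PDPN, a surface glycoprotein of early germ cells, by 2.03 ± 0.74, and POU5F1 by 3.11 ± 1.04. The last 2 are averages of unequal changes. PDPN went from 9.04 to 105 CPM in the rhesus and from 64.2 to 127 CPM in the cynomolgus line. POU5F1 went from 4.26 to 178 CPM in the rhesus and from 50.1 to 142 CPM in the cynomolgus line. NLRP7, a maternal-effect gene of the naive pluripotency list, differed by 5.01 ± 1.07, FAP, a protease of activated fibroblasts, by 2.83 ± 0.45, and LMO2, a blood and endothelial co-factor, by 2.40 ± 0.44. The change of NLRP7 was unequal too, from 0.0263 to 7.46 CPM in the rhesus and from 1.39 to 14.4 CPM in the cynomolgus line. HAND1 and BMP5 were lower at day 4 in both lines, by -1.32 ± 0.30 and -1.56 ± 0.39. ACTA2, smooth muscle actin, was higher by 1.65 ± 0.59 and CDKN1A, the p53-induced cell cycle inhibitor, by 1.30 ± 0.26.

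As groups, 8 of 9 early germ cell genes were higher at day 4 and 11 of 12 mesoderm genes were lower (camera adjusted p = 6.8e-05 and 4.87e-05; adjusted p = 0.547 for both with an estimated correlation). The lists of fibroblast (adjusted p = 0.00141), endothelial and blood (0.0041), immediate-early (0.0076), glycolysis (0.00954), p53 target (0.011) and S phase genes (0.0271) were also placed higher and cholesterol synthesis (0.0141) lower by camera. With an estimated correlation the adjusted p of these 7 lists ran from 0.547 to 0.617. The early germ cell call held with any library left out. Without the day 2 library of the rhesus line the calls for mesoderm, glycolysis, p53 target and S phase genes ended and immediate-early genes turned lower without a call. Without that of the cynomolgus line the calls for fibroblast, endothelial and blood and S phase genes ended and cholesterol synthesis turned higher without a call. Without the day 4 library of the rhesus line immediate-early, p53 target and S phase genes lost the call, without that of the cynomolgus line fibroblast, glycolysis and cholesterol genes, and without the naive library of the cynomolgus line S phase genes. Adjusted over the list alone, 2 early germ cell genes, 1 fibroblast gene, 1 endothelial and blood gene and 1 immediate-early gene were higher and 0 mesoderm genes lower.

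edgeR called 0 of 14663 genes between day 4 and day 2, where 942 had an unadjusted p under 0.05, and DESeq2 called 154 genes, 104 higher and 50 lower, including NANOS3, DND1, POU5F1, NLRP7, FAP, LMO2, BMP5 and CDKN1A. In simulated counts of this size with 200 changed genes, edgeR recovered 0 of 65 genes changed 2-fold, 43.8% of genes changed 4-fold and 69.4% of genes changed 8-fold. In the simulation changes of 2-fold were thus out of reach, and many larger ones were missed as well. edgeR also called 10 unchanged genes beside 32 and 43 recovered at 4 and 8-fold, more than the 0.05 threshold allows. The simulated counts held no difference between lines, so the 0 calls in the data do not argue against large changes.

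Day 4 EBs were also compared with naive cells. Some early germ cell genes and most of the mesoderm, fibroblast and mesenchymal genes measured were above their naive level. NANOS3 rose by 7.90 ± 0.99, PRDM1 by 3.02 ± 0.49 and ARID5B by 4.61 ± 0.35 (log2 ± SE; edgeR adjusted p = 0.0135, 0.0225 and 0.00745), while TFAP2C differed by 3.47 ± 1.29 without passing (adjusted p = 0.122); without either day 2 library TFAP2C passed. HAND1 rose by 13.27 ± 0.52 and TTR by 12.74 ± 0.43. SOX2 fell by 8.77 ± 0.54, USP44 by 7.43 ± 0.25 and DNMT3B by 3.78 ± 0.29, whereas POU5F1 was at 159.8 ± 25.3 CPM at day 4 against 219 ± 34.4 CPM in naive cells (-0.35 ± 0.89, adjusted p = 0.812). Its fitted value was 0.47 without the naive library of the rhesus line, 0.46 without the day 4 library of the cynomolgus line and -1.79 without that of the rhesus line.

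Of 9 early germ cell genes 4 rose and 1 fell, and of 6 naive pluripotency genes 4 rose and 1 fell, NLRP7 among the 4 (from 0.138 to 10.9 CPM, edgeR adjusted p = 0.0239). Apart from KLF4, the measured naive genes were at 1.04 CPM or less in naive cells and had little room to fall. Their rises thus say little of a naive programme. Of 14 fibroblast genes 10 rose and 0 fell (FAP, 9.69 ± 0.69), as did 10 of 14 mesenchymal genes (COL4A1, 4.00 ± 0.28), 9 of 14 amnion and trophoblast genes (IGFBP3, an IGF-binding protein, 5.06 ± 0.63), 8 of 12 mesoderm genes and 5 of 9 endothelial and blood genes. Of 14 endoderm genes 5 rose and 1 fell, and 4 of 12 epithelial genes rose. Of 16 primed pluripotency genes 2 rose and 10 fell, and in the lists that follow 0 rose: 3 of 11 core pluripotency genes fell, 5 of 12 neural ectoderm genes, 11 of 20 S phase genes (PCNA, -1.04 ± 0.16), 5 of 17 cholesterol synthesis genes, 4 of 19 glycolysis genes, 3 of 20 G2M genes and 1 of 11 immediate-early genes. Adjusted over the list alone, 4 early germ cell, 5 naive, 13 fibroblast, 10 mesenchymal, 13 amnion and trophoblast and 8 mesoderm genes rose, and 6 core, 11 primed, 8 neural, 11 S phase, 5 cholesterol, 7 glycolysis, 3 G2M and 1 immediate-early genes fell. On the same basis 1 gene each of the early germ cell, naive, mesenchymal and amnion and trophoblast lists fell.

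edgeR called 2469 of 14663 genes between day 4 and naive, 1519 higher and 950 lower, and DESeq2 called 3712. With camera's preset correlation 17 of 28 lists passed, 9 up and 8 down, with an adjusted p from 5.48e-06 for fibroblast to 0.0372 for glycolysis genes, and with an estimated correlation 0 passed, at an adjusted p from 0.547 to 0.617. Single omissions ended the call for naive pluripotency (either day 2 library, or the naive or day 4 library of the cynomolgus line), glycolysis (naive or day 4, rhesus line) and epithelial genes (naive, cynomolgus line). Without either naive library NANOS3, NLRP7 and PCNA missed the threshold, and without that of the rhesus line ARID5B, FAP, IGFBP3 and PRDM1 did too. Without the day 4 library of the rhesus line PRDM1 and PCNA missed it, and without that of the cynomolgus line IGFBP3 and PCNA. The count of called genes fell without any naive or day 4 library and rose without either day 2 library. Each such fit leaves 1 library in a stage, so a fall cannot show that the calls rest on that library. In simulated counts 19 unchanged genes were called beside 4, 41 and 50 recovered at folds of 2, 4 and 8, more than the 0.05 threshold allows.

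The 2 lines were compared over all stages, since the design text contrasts them. No gene passed the test. Epithelial genes were among those furthest apart: GRHL2, a transcription factor of epithelial identity, was higher in the cynomolgus line by 6.23 ± 0.45 and RAB25, an epithelial trafficking GTPase, by 5.27 ± 0.38 (log2 ± SE; edgeR adjusted p = 0.152 for both), in all 3 stages. CDH1, which encodes E-cadherin, differed by 4.61 ± 1.12 (adjusted p = 0.317), with 0.131 CPM in the rhesus and 35.3 CPM in the cynomolgus line at day 2. CDH3 differed by 2.76 ± 0.45, KRT7 by 2.94 ± 0.71, KRT18 by 2.11 ± 0.38 and BMP4, a ligand that induces amnion and germ cell fate, by 1.63 ± 0.18, all higher in the cynomolgus line at each stage. ZEB1 (-1.36 ± 0.22), ZEB2 (-1.46 ± 0.17) and TWIST2 (-1.18 ± 0.28), repressors of epithelial genes, and FAP (-2.25 ± 0.43) were lower in it at each stage.

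Of 12 measured epithelial genes 12 were higher in the cynomolgus line, with a median log2 difference of 2.14; 0 passed over all genes and 10 passed adjusted over the list alone. Of 14 mesenchymal genes 12 were lower in it; 0 passed over all genes, and adjusted over the list alone 5 were lower and 1 higher. All 7 primitive streak genes and 16 of 17 cholesterol synthesis genes were higher and all 11 immediate-early genes were lower, again with 0 passing over all genes, and adjusted over the list alone 0, 0 and 1. Of endoderm genes 12 of 14 were higher, and 10 of 14 fibroblast and 10 of 11 neural ectoderm genes were lower, with 0 passing over all genes.

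edgeR called 0 of 14005 genes between the lines, where 1580 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0906, and DESeq2 called 473, 331 higher and 142 lower in the cynomolgus line. Without the filter on low counts edgeR called 3 genes, GRHL2, RAB25 and HSBP1L1 (the last chosen for naming after its value was seen; 7.71 on the log2 scale). Line, species, labelled sex and handling cannot be told apart in these libraries. The counts of named cell types differed as well, but they cannot show that the mix of cells differed. Clusters were named by enrichment over the other cells of the same line, so a name need not mean the same in both lines. At day 2 amnion or trophoblast-like cells were 5372 of 8716 in the cynomolgus and 123 of 7442 in the rhesus line, where 1896 and 4236 cells stayed unnamed. Sums over whole libraries cannot part a different mix of cells from a difference within cells.

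**Figure D2:**
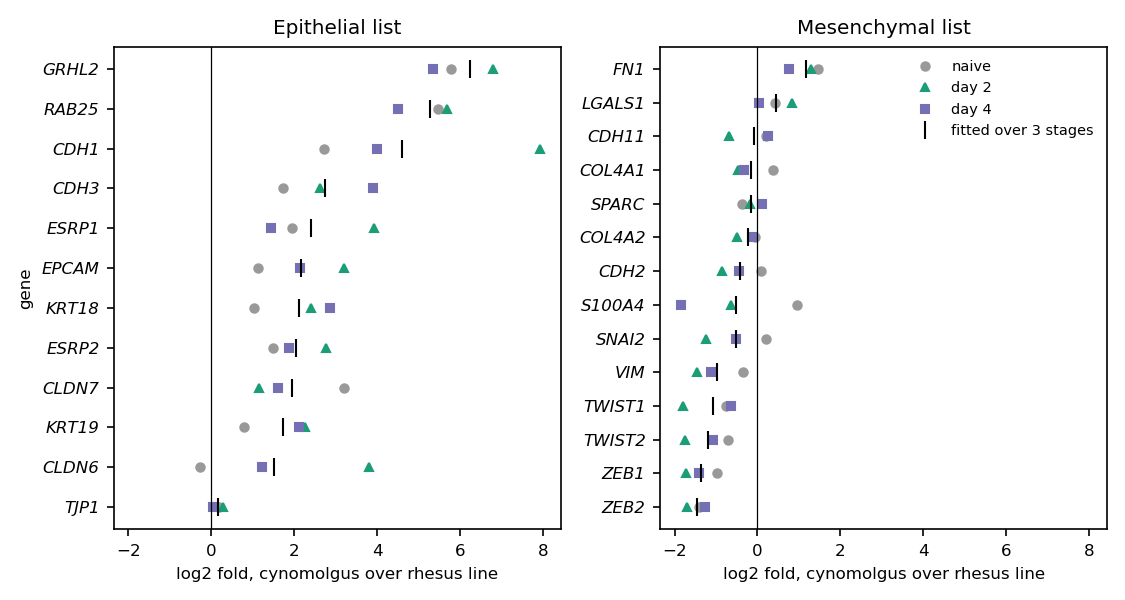
Log2 fold of the cynomolgus over the rhesus line for the measured genes of the epithelial (left) and mesenchymal (right) lists, at each stage (symbols) and fitted over 3 stages (bars). All 12 epithelial genes lie to the right of 0 in the fit, up to 6.23 for GRHL2, and 12 of 14 mesenchymal genes lie to the left.

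Germ cell-like cells were gated by UMIs of at least 2 of TFAP2C, PRDM1 and NANOS3, the measured genes of the human and monkey germ cell programme fixed for the gate. In the 4 EB libraries most of the core pluripotency and germ cell genes measured were higher in gated cells than in the other cells, and most of the fibroblast, mesenchymal and mesoderm genes were lower. POU5F1 was higher by 3.15 ± 0.54, DND1 by 3.00 ± 0.31, PDPN by 3.13 ± 0.48 and CXCR4, the receptor that guides germ cell migration, by 1.77 ± 0.21 (log2 ± SE; edgeR adjusted p = 0.0035, 0.000365, 0.00207 and 0.000732). IGF2, a fetal growth factor, was lower by -4.34 ± 0.25, POSTN by -3.92 ± 0.23 and CDH11 by -2.66 ± 0.16 (adjusted p = 8.3e-05 for each). SOX2 did not differ past the threshold (0.55 ± 0.37, adjusted p = 0.325).

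Of 10 core pluripotency genes 6 were higher and 1 lower in gated cells, with DPPA4 at 2.60 ± 0.37, L1TD1 at 2.37 ± 0.28 and NANOG at 2.10 ± 0.36, the last in 3 of 4 libraries and not with all 3 genes required. Besides the gate genes, which were left out of the test, 4 of 6 early germ cell genes were higher and 0 lower, and so were 2 of 3 late germ cell genes and 6 of 19 S phase genes (MCM2, a replicative helicase subunit, 1.03 ± 0.15). Of 12 primed pluripotency genes 1 was higher and 4 lower, and of 5 naive pluripotency genes 2 were higher and 2 lower. Of 7 endothelial and blood genes 3 were higher and 2 lower. MESP1, an early mesoderm factor, was higher by 3.02 ± 0.28, LMO2 by 2.81 ± 0.31, PECAM1, the adhesion molecule CD31, by 2.40 ± 0.38 and ETV4, a target of FGF signalling, by 2.28 ± 0.36. GREM1, a BMP antagonist (3.21 ± 0.50), the BMP target ID1 (0.89 ± 0.17), NMU, the neuromedin U precursor (3.13 ± 0.56), and PPARA, a nuclear receptor of fatty acid use (2.96 ± 0.39), were higher as well.

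Of 14 fibroblast genes 0 were higher and 12 lower in gated cells (COL3A1, -3.26 ± 0.28), of 14 mesenchymal genes 0 and 11 (ZEB2, -3.09 ± 0.28), and of 10 mesoderm genes 0 and 9 (HAND2, -3.14 ± 0.21, and MEIS2, -3.17 ± 0.26). DDR2, a collagen receptor, was lower by -3.74 ± 0.33. Of 13 amnion and trophoblast genes 0 were higher and 5 lower (IGFBP3, -3.17 ± 0.24, and KRT18, -1.82 ± 0.32), of 12 endoderm genes 2 and 5 (TTR, -1.25 ± 0.25), of 12 epithelial genes 1 and 5, of 9 WNT targets 0 and 5, of 11 FGF and ERK targets 2 and 5, of 9 BMP targets 2 and 3, of 6 STAT3 targets 0 and 3 (MYC, -2.54 ± 0.17), of 19 glycolysis genes 1 and 5, and of 9 DNA methylation genes 0 and 2 (DNMT3A, -1.03 ± 0.13). CD24, of the primed list, was lower by -2.31 ± 0.22. Adjusted over the list alone the numbers were 6 higher for core pluripotency, 4 for early germ cell, 11 for S phase, 3 for naive pluripotency, 1 for primed pluripotency and 3 for endothelial and blood genes, and 12, 11 and 9 lower for fibroblast, mesenchymal and mesoderm genes.

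edgeR called 3204 of 12533 genes between gated and other cells of the same library, 1334 higher and 1870 lower. With all 3 gate genes required it called 2162, 643 higher and 1519 lower. Against depth-matched ungated cells edgeR called 2759 of 10091 genes, 1292 higher and 1467 lower. The gated sum of the day 2 library of the rhesus line held only 24 cells, and without that library edgeR called 3251 genes. Without the library as replicate block it called 1367, and POU5F1, CXCR4, MESP1, NANOG, KRT18, ID1 and TTR were not among them. Without the day 4 library of the cynomolgus line it called 1799. In simulated counts with 200 changed genes edgeR recovered 52.5%, 85.5% and 97.1% of genes changed 2, 4 and 8-fold and also called 47 unchanged genes, more than the 0.05 threshold allows.

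**Figure D3:**
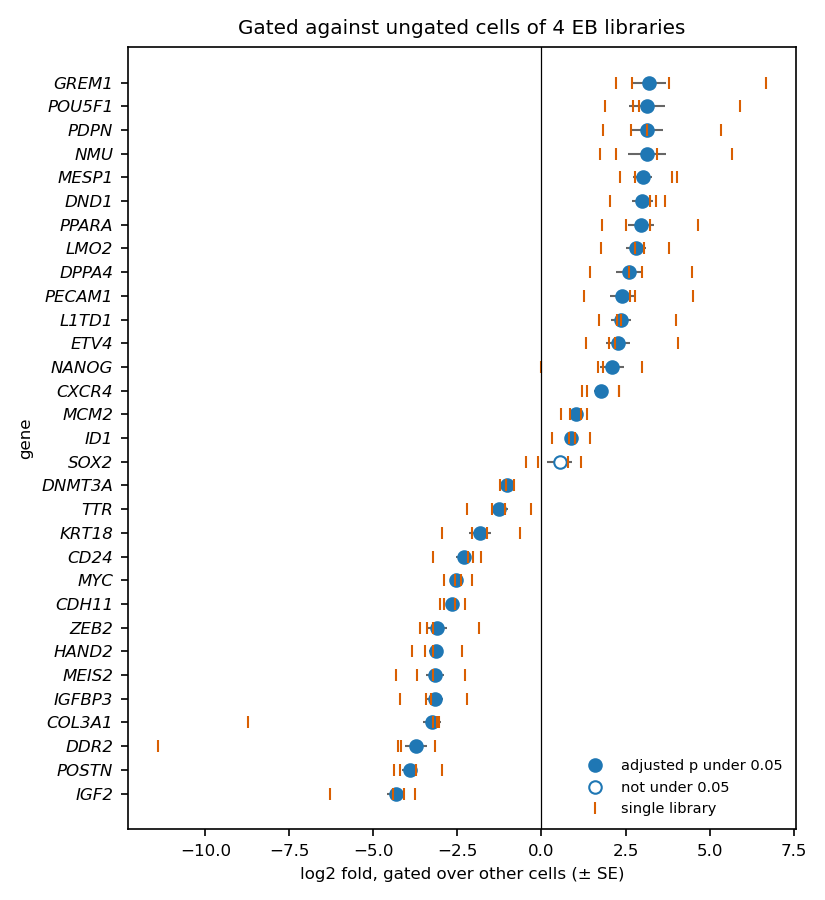
Log2 fold of gated over other cells for 31 genes in 4 EB libraries (circles with SE, filled where the adjusted p is under 0.05; ticks are single libraries). POU5F1, PDPN, DND1 and GREM1 lie near 3, SOX2 is the open circle at 0.55, and IGF2 lies lowest at -4.34.

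Gated cells were counted in each library, with exact Clopper-Pearson intervals of 95% that cover counting error only. They made up 0.198% (0.095 to 0.364) of naive cells of the rhesus line and 0.477% (0.291 to 0.735) of those of the cynomolgus line. At day 2 they made up 0.322% (0.207 to 0.479) in the rhesus line and 3.81% (3.42 to 4.23) in the cynomolgus line, and at day 4 11.7% (10.97 to 12.5) and 10.0367% (9.27 to 10.8). With each cell thinned to 4000 UMIs the day 2 shares were 0.147% and 1.64% and the day 4 shares 4.29% and 3.57%, and 0 of 5051 and 0 of 4196 naive cells passed, with upper bounds of 0.0730% and 0.0879%. Endoderm-like cells, taken as a background, passed the gate in 0.403% (0.0102 to 2.23) of cells in the rhesus and 2.54% (1.27 to 4.50) in the cynomolgus line at day 2, and in 4.46% (2.33 to 7.66) and 2.55% (0.833 to 5.85) at day 4. Their median UMIs were 11316, 8083, 11949 and 13154.5 in that order, against 11307, 10062.5, 11527.5 and 11980 in gated cells. Pass rates varied widely over other clusters. The gate passed 0 of 2762 mesoderm-like and 0 of 4236 unnamed cells of the rhesus line at day 2 (upper bounds 0.133% and 0.0870%), 0.503% of 5372 amnion or trophoblast-like cells of the cynomolgus line at day 2, and 0.262% and 0.259% of fibroblast-like cells at day 4. Rates were higher in amnion or trophoblast-like cells of the rhesus line, 13.8% at day 2 and 10.6% (9.09 to 12.2) at day 4, and in unnamed cells of the cynomolgus line, 4.32% and 8.36%, where a single cluster held 82 of 82 gated cells at day 2 and 324 of 338 at day 4. Of the 24 gated cells of the rhesus line at day 2, 17 were amnion or trophoblast-like and 6 early germ cell-like. These classes turn with the clustering: at Leiden resolution 0.5 they held 14 and 117 cells of that library, against 123 and 17. Both day 2 shares lay within the interval of endoderm-like cells, which rests on 1 of 248 and 11 of 433 cells. This cannot show that the gated cells are background. In the cynomolgus line at day 2 they were concentrated: 142 of 309, 82 of 216 and 70 of 360 cells passed in some clusters. In the largest clusters 19 of 3302, 7 of 1619 and 0 of 1564 passed. Both day 4 shares lay above those of endoderm-like and fibroblast-like cells. That of the rhesus line overlapped that of its amnion or trophoblast-like cells, but this class cannot serve as a background. A single cluster held 1528 of its 1592 cells and 167 of its 168 gated cells, which also count in the library share. At Leiden resolution 0.5 the class held 60 cells of that library, and the early germ cell-like class held 3270 against 1742. A UMI of TFAP2C alone was found in 2.75% of day 2 cells of the rhesus and 43.7% of those of the cynomolgus line. There was no replicate of any share and no test.

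**Figure D4:**
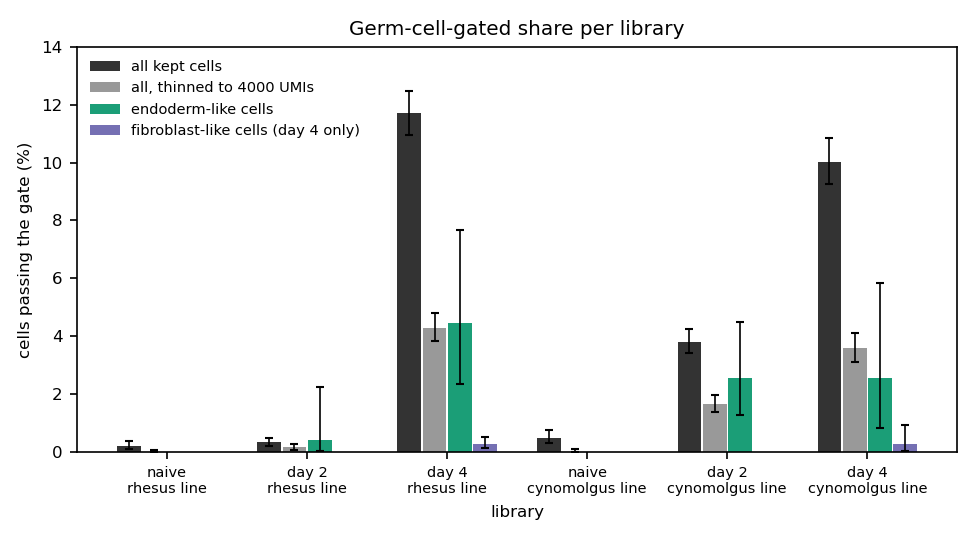
Share of cells passing the germ cell gate (percent, with exact 95% intervals) in each library, for all kept cells, for all cells thinned to 4000 UMIs, and for endoderm-like and fibroblast-like cells. The day 4 libraries reach 11.7% and 10.0367%, and the day 2 library of the rhesus line stands at 0.322%.

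Cells of each line were clustered and clusters named by fixed markers. Endoderm-like clusters, led by TTR and APOA1, took similar shares in all EB libraries: 3.33% and 3.78% of cells of the rhesus line at day 2 and day 4, and 4.97% and 3.42% of cells of the cynomolgus line. Early germ cell-like clusters, 1 in the rhesus and 2 in the cynomolgus line, took 0.228% and 24.5% in the rhesus line and 7.68% and 10.6% in the cynomolgus line, and CALB1, TFAP2C and NMU were among the leading genes of that of the rhesus and the larger of the cynomolgus line. The gate passed 35.3% and 37.0% of these cells in the rhesus line at day 2 and day 4. In the cynomolgus line it passed 46.0% and 48.3% in the larger cluster, and 70 of 360 and 29 of 193 cells in the other. A cluster of 216 cells at day 2 and 784 at day 4 in the cynomolgus line had 7 germ cell markers but stayed unnamed for its leading genes, and 38.0% and 41.3% of its cells passed the gate. Amnion or trophoblast-like cells with TFAP2A, KRT7 and KRT18 made up 61.6% of day 2 cells of the cynomolgus line, mesoderm-like cells with HAND1, HAND2 and KDR 37.1% of day 2 cells of the rhesus line, and fibroblast-like cells with COL1A1 and COL3A1 48.3% of its day 4 cells. At a coarser clustering the mesoderm-like share was 88.4% and the early germ cell-like share at day 4 was 45.9% in the rhesus and 24.3% in the cynomolgus line. With 4000 variable genes these day 4 shares were 12.7% and 8.73%, and with doublet calls kept 11.7% and 8.70%. With 1 library per line and stage, and clusters built within each line, these shares were not tested. X-linked genes were not compared between the lines, as the chromosome table used here is of another assembly than the counts.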

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

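Of the tests below, only that on the share of cells with an RPS4Y1 UMI was set before its result was seen; the other tests were chosen after.

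Genes of the Y chromosome were transcribed in the line labelled female at levels similar to those in the line labelled male. Male cells mixed in as the minority of female libraries are argued against, as the lowest log2 ratio over 9 genes and 3 stages was -0.77, less than a 2-fold deficit. A smaller admixture of female cells stays open: the thinned share of cells with an RPS4Y1 UMI was at most 0.323 percentage points higher in the line labelled male, but at shares of 97.6% and more it is saturated. Reads of X-linked copies, counted at a constant share for their Y-linked relatives, are argued against for UTY, ZFY and EIF1AY. Between naive cells and day 2 their Y to X ratios in the cynomolgus line went from 1.24 to 2.83, 1.88 to 5.33 and 1.42 to 0.962. The ratio moved beyond counting error and the same way in both lines in 6 of 8 gene pairs. Counting error is small for abundant genes, so small shifts pass as well. For RPS4Y1 (0.443 to 0.392 in the cynomolgus line) and DDX3Y (1.27 to 1.36) shared reads stay open. A cell line that carries a Y chromosome may be the source (lowest stage median of the log2 ratio -0.41). The label female speaks against a Y chromosome, but the growth text of the labels pairs female with XY. Whether both sets of libraries come from a single line stays open, with 0 genes at 10 CPM or more in each library of 1 line and under 0.5 CPM in each of the other.

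Few cells of the rhesus line passed the germ cell gate at day 2, against 3.81% in the cynomolgus line. Shallower cells are argued against, as the share was 0.147% with each cell thinned to 4000 UMIs, against 1.64%. A swap of the day 2 libraries between the lines is argued against as well: of 66 genes at least 2-fold apart between the lines in naive and in day 4 libraries, 15.2% (exact interval 7.51 to 26.1) went the other way at day 2. The interval takes these genes as independent, which genes of 1 pair of libraries per stage need not be. The fold minimum of that test was lowered to 2 after a minimum of 4 had left 3 genes. Whole profiles were less clear. The day 4 library of the rhesus line correlated by 0.932 with the day 2 library of its own line and 0.934 with that of the other line. For the cynomolgus line these values were 0.979 and 0.916. A later start of the rhesus line may explain it, since the thinned day 4 shares stood at a ratio of 1.20 (rhesus to cynomolgus), but with 1 library per line and stage it cannot be told apart from a difference between cultures or species.

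Some named genes moved at least 2-fold in opposite ways in the 2 lines; the difference between lines was not tested. Between naive cells and day 2, TFAP2C went by -1.47 in the rhesus line and 3.56 in the cynomolgus line on the log2 scale. Between day 2 and day 4, OTX2 went by 3.00 and -1.58, HES5, a Notch target, by 1.68 and -4.00, and CDH1 by 2.08 and -1.85. Most of these levels were near 0, so the folds are uncertain. OTX2 went from 0.223 to 1.87 CPM in the rhesus and from 0.768 to 0.248 CPM in the cynomolgus line. HES5 went from 0.131 to 0.446 CPM and from 0.84 to 0.0413 CPM, and CDH1 from 0.131 to 0.595 CPM and from 35.3 to 9.77 CPM, in the same order.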

How the results depend on the processing

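The feeder-like clusters were left out as a test chosen after the data were seen; it called 3332, 0, 2502 and 0 genes (day 2 against naive, day 4 against day 2, day 4 against naive, lines). RLE size factors, all barcodes and thinned sums left these counts within 1.5 times. Genes called for day 2 against naive were 1764 with only the 4 libraries compared and 886 against a minimum fold of 2; for day 4 against naive 3712 in DESeq2 and 814 against a minimum fold of 2. DESeq2 called 154 genes between day 4 and day 2 and 473 between lines, and edgeR without the filter on low counts 3 between lines. Without the replicate block, that is the pairing by line, edgeR called 2704, 0 and 1901 genes between stages; without the library block it called 1367 for gated cells. With 1 library left out, which assumes that a lone library varies like the others, counts ran from 445 to 2753 (day 2 against naive), 161 to 3639 (day 4 against naive), 1799 to 3251 (gated cells) and 0 to 0 (day 4 against day 2, and lines), and called lists from 13 to 15, 6 to 11 and 15 to 17. With an estimated correlation 0, 0 and 0 lists were called. TFAP2C at day 2 against naive ran from -1.39 (without the day 2 library of the cynomolgus line) to 3.49 (without that of the rhesus line). POU5F1 at day 4 against naive was 0.47 without the naive library of the rhesus line, 0.46 without the day 4 library of the cynomolgus line and -1.79 without that of the rhesus line; the cause was not tested. Over named genes of all comparisons, single omissions left 554 values on their side, with 42 weaker (23 of them without the naive library of the rhesus line and 10 without that of the cynomolgus line), 5 stronger and 3 reversed, and other settings 864, with 25 weaker and 23 stronger.

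Gated shares with all 3 genes were 0%, 0.0269% and 1.57% (rhesus line; naive, day 2, day 4) and 0%, 0.161% and 1.10% (cynomolgus line), and thinned 0%, 0.147%, 4.29%, 0%, 1.64% and 3.57%. At Leiden resolution 0.5 the germ cell-like shares were 1.57% and 45.9% (rhesus line, day 2 and day 4) and 10.2% and 24.3% (cynomolgus line); at resolution 2, 0.954%, 36.6% and 6.52% for the first 3; with 4000 variable genes 0.107%, 12.7%, 6.61% and 8.73%; with doublet calls kept 11.7% (rhesus, day 4), 6.59% and 8.70% (cynomolgus). The amnion-like share of the cynomolgus line at day 2 was 65.4% at resolution 2 and 59.8% with doublets kept. The mesoderm-like share of the rhesus line at day 2 was 88.4%, 66.4%, 46.4% and 35.4% under resolution 0.5, resolution 2, 4000 genes and doublets kept, and its fibroblast-like share at day 4 47.1% and 37.5% at resolution 0.5 and 2. Neural-like naive cells were 0% in the rhesus line with 4000 genes and 0% in the cynomolgus line with 4000 genes, at resolution 0.5 or with doublets kept. The cause was not tested. Not run were X-linked genes, with their alternatives of genes with at least 100 UMIs and of all barcodes, and the gate of any 2 of the genes, which equals the gate used.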

Other observations

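The tests on small clusters below and the counts of other splits were chosen after the results were seen, as was the feeder-like grouping, when a first rule for feeder cells had held 0 cells.

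Naive cultures held small groups of cells with genes of differentiated lineages. In the rhesus line 8.73% of naive cells (441 cells) fell in a neural ectoderm-like cluster led by CRABP1, PTN and ZBTB16, with ZIC1, HES5 and TUBB3 as markers. In the cynomolgus line 304 naive cells (7.24%) fell in a cluster led by CRABP1, PTN and FGFBP3, with PAX6, ZIC1, HES5, TUBB3, POU3F2 and STMN2 as markers. A cluster of the cynomolgus line with 343 naive cells (8.17%) was named primitive streak-like by MIXL1, SP5 and CER1. It also had 4 endoderm markers, with HHEX and FOXA2 among its leading genes, so the name is uncertain. The neural-like names were lost with 4000 variable genes in both lines.

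Small clusters led by genes without a symbol held 89 cells of the rhesus and 76 cells of the cynomolgus line, between 0.115% and 1.05% of each library. Damaged cells stay open: the median mitochondrial share was 0.297% in the rhesus line against 3.25% in other cells, but cells stripped of cytoplasm can be low as well. Other clusters, with RPS4Y1 at 2078 CPM or more, had medians of 0.119% to 0.252%. Mouse feeder cells, on which the naive cells were grown, may be a source. All naive cells named fibroblast-like by the markers, 21 in the rhesus and 44 in the cynomolgus line, lay in these clusters. But RPS4Y1 stood at 34.6% of its level in other cells in the cynomolgus line and 27.7% in the rhesus line, which does not decide between feeder cells with free monkey RNA and monkey cells. No other explanation was tested.

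Between the lines the real split called 0 genes in edgeR, with 1580 at an unadjusted p under 0.05 and 473 called by DESeq2. The highest of the other splits of the 6 libraries called 0. With 0 genes in the real split all 10 of 10 splits must give as many, so this count decides nothing. For gated cells the real split called 3204 genes and the highest of the other splits 0, 1 of 8 splits. In both the splits are too few for a share under 0.05.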
